A study of Homo sapiens with 54 samples.

How the data were processed

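The study sequenced total RNA from biopsies of metastases in patients with colorectal cancer (CRC) or pancreatic adenocarcinoma (PDAC). Per the labels' protocols, tissue was snap frozen, RNA was extracted with a kit that recovers DNA and RNA together, and libraries were made from 10 ng of RNA with a stranded total RNA kit and read in pairs on a NextSeq 500 with 150 cycles. Such kits read all RNA classes, so unspliced, mitochondrial and repeat RNA appear beside mRNA.

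The authors deposited a table of raw counts per gene and per repeat family, whole numbers for each library. Per the submitters' processing notes, HTSeq and DESeq2 were among the tools and hg38 or GRCh38 the genome build, with no versions. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes cannot be assigned with certainty. A deposited table of normalized signal holds the same features. Each of its values times 1 size factor per library gave a whole number, equal to the raw count within 0.001 counts for 100% of values, with size factors from 0.0324 to 2.72. It was used only to take over those size factors.

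The count table holds 60719 gene features and 16108 repeat features, of which 14141 are simple repeats, low-complexity stretches or ribosomal RNA. Library sizes and tests used genes only. Gene identifiers were matched to GENCODE 29 on GRCh38 without their version. Of the genes, 58488 matched and 38732 had the same version. This annotation served for coordinates alone.

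Of 54 labelled samples, 53 had a column. The remaining sample was not analysed here, and 1 column that matches no labelled sample was not used. Groups are cancer type by time point as labelled. 1 Pre-Tx library was left out of the fits because its cancer type contradicts the label of the other libraries with its number, which left 52 libraries in the fits over time (22 Pre-Tx, 19 Pre-xRT and 11 Post-xRT) and 22 in the baseline fit. The runs were spread unevenly, since the 10 PDAC Pre-Tx and 5 PDAC Post-xRT libraries were all of run NS82.

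The number in a library's title was taken as the patient. As a check, each library's deviations from its group mean and run were correlated over 14785 genes, leaving out the CRC Pre-Tx library with the fewest genes detected. The 33 remaining pairs with the same number had a median r of 0.273 and the 1242 other pairs of the same fit a median of -0.025. 25 of the 33 were over 0.1, and 14 of 45 libraries with a partner correlated best with their own number. Transcripts of the sex chromosomes disagreed in 0 of 19 numbers with more than 1 library. The closest pair of libraries (r = 0.975, same number) still differed beyond sampling noise, with a chi-square of 14.8 per degree of freedom over 14309 genes, so no library was treated as a copy. Libraries of different numbers are different patients under this reading, so p-values measure the spread between patients and biopsies. Libraries of 1 patient at different times were treated as independent in the main fits, and fits with the number as a block were run beside them.

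Genes were filtered with edgeR's filterByExpr, scaled by TMM and tested with edgeR's quasi-likelihood F test with robust dispersion, two-sided, with Benjamini-Hochberg adjustment at 0.05. The fits over time had time, cancer type and run as terms. Those within a cancer type had a mean per group, with run, and the baseline fit had cancer type and run. Standard errors were taken from the fold change and its test statistic. Normalised read counts (CPM) use TMM library sizes, and log2 CPM has a prior count of 2. limma's camera tested 38 gene lists of 8 to 25 genes (577 genes, 573 matched) fixed before the data were examined, with a preset correlation of 0.01 between genes and again with an estimated one, and adjustment over the lists of a comparison. The lists cover immune, stromal, epithelial and other tissue cell types and stress, interferon and growth programmes. Gene counts per list are also adjusted over the list alone. Ratios of summed reads have exact binomial intervals at 95% confidence, and where a group had no read the bound uses 3 counts over the group. Both cover counting error only.

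Named genes follow a rule set before the data were examined. It takes the 8 largest rises and 8 largest falls past the threshold with a mean log2 CPM of at least 1, up to 3 genes per list by p, 22 genes named whatever their result, and the 6 smallest p where fewer than 5 genes pass. Some genes that it names are not reported here. It was extended to CRC alone and to the Pre-xRT contrast of the cancer types after their values were seen.

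Alternatives chosen before the data were examined were other size factors, DESeq2, limma-voom, no or a stricter low-count filter (10 counts), no run term, run NS82 alone, the conflicting library kept, the libraries of low depth (less than the median divided by 3) left out, the hepatocyte list as a covariate, the block and single libraries left out. Chosen after seeing the data were fits without the CRC Pre-Tx library with the fewest genes detected (4606, the next having 13529), the authors' size factors, the epithelial list as a covariate, some further fits in CRC, among them the libraries of run NS88 alone, list tests without single libraries, exact sign-flip tests within patients (16, 9 and 10 pairs, smallest possible p 3.1e-05, 0.00391 and 0.00195) and the repeat families. Work was done in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and data.table (1.17.8).

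The procedure was tested on simulated data made from the real means and library sizes, with 50 genes changed at each of 4 sizes. For Pre-xRT against Pre-Tx it recovered 32, 70, 94 and 100% of genes changed 2, 4, 8 and 16 fold, for Post-xRT against Pre-xRT 28, 70, 92 and 98%, for the baseline contrast 4, 60, 84 and 96%, and for CRC alone 18, 72, 86 and 92%. It called 12, 5, 6 and 14 unchanged genes. A simulated list of genes changed 2 fold passed with both correlations, and 0 of 37 random lists did. Changes of 2 fold in single genes are thus mostly below what these depths and groups can show. Each gene was drawn independently around a fit without patients. Genes that move together, as those of a tissue whose share differs between biopsies, were therefore not simulated. The shares recovered may be higher than in the real data, and the list check does not cover correlated genes.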

Results

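RNA was measured in biopsies of metastatic tumours from a phase II trial of nivolumab, an antibody against the T-cell receptor PD-1, and ipilimumab, an antibody against CTLA-4, combined with radiation. The patients had microsatellite-stable colorectal cancer (CRC) or pancreatic adenocarcinoma (PDAC) that had been treated with chemotherapy before, and the biopsied sites lay outside the irradiated field. Biopsies carry 3 time labels relative to treatment (Tx) and radiation (xRT). In the fits over time, CRC gave 12 Pre-Tx, 12 Pre-xRT and 6 Post-xRT libraries, and PDAC gave 10, 7 and 5. The biopsied organ and the clinical response are not given in the sources used here. Each library's total over gene and repeat features lay between 1200233 and 16061213 counts (median 7528818), of which genes held 412159 to 7222840 (median 4393478). The 42 libraries of sequencing run NS82 had a median of 4887269 gene counts and the 11 of run NS88 a median of 800636, so run was a term in the models of all libraries described here. The number of genes detected ranged from 4606 to 27400. The lowest value belongs to 1 library of the CRC Pre-Tx group in which mitochondrial ribosomal RNA made up 47.5% of gene counts. Fold changes are log2 values with standard errors (SE). Gene p-values come from edgeR's quasi-likelihood test and list p-values from limma's camera with a preset correlation between genes, all two-sided with Benjamini-Hochberg adjustment. Gene positions are on GRCh38 from GENCODE release 29.

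The comparison of Pre-xRT with Pre-Tx biopsies addresses what differed between the baseline sample and the sample taken before radiation. Genes of hepatocytes, the main cell type of the liver, were lower at Pre-xRT, while genes of dividing cells were higher (19 against 22 libraries). The 25 measured hepatocyte genes fell by 3.60 on the log2 scale on average (camera adjusted p = 4.1e-28, or adjusted p = 0.43 with an estimated correlation). The 20 proliferation genes rose by 1.22 and the 17 replication-dependent histone genes by 1.10 (camera adjusted p = 1.7e-08 and 1.4e-05, and adjusted p = 0.992 for both with an estimated correlation). Over all 18531 genes tested, edgeR called 1 gene and 3204 genes had an unadjusted p under 0.05.

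The genes nearest the threshold that are described here did not pass. They were SAA2-SAA4, a readthrough transcript of the serum amyloid A genes that shares reads with them (-5.86, SE 1.16, edgeR adjusted p = 0.0515), NXPE4 (4.74), PADI2 (2.41), DUSP18 (1.0) and NXPE1 (3.73), the last 4 with edgeR adjusted p between 0.0557 and 0.0805. DESeq2 called 1463 genes in the same comparison (237 higher and 1226 lower) and limma-voom 1, and the paired edgeR fit called 3, all lower: FNDC5, CYP7A1 and GDF2, which were named after their values were seen. Within run NS82 alone edgeR called 1912 genes (445 higher and 1467 lower), and the hepatocyte, proliferation and histone means were -5.27, 1.71 and 1.38. Run NS88 held no Pre-Tx library of PDAC, so only CRC was compared within it. With 4 libraries at each time there, edgeR called 0 of 11933 genes, 148 had an unadjusted p under 0.05 and no other tool was run. Within this run the hepatocyte and proliferation lists did not pass. Their means were -0.028 over the 7 hepatocyte genes tested (camera adjusted p = 0.851) and -0.033 with a test direction above 0 (camera adjusted p = 0.931). Histone genes rose by 0.60 (camera adjusted p = 0.0139, and adjusted p = 0.936 with an estimated correlation). A fall of hepatocyte genes could hardly show here. The hepatocyte gene ALB lay between -0.96 and 5.93 log2 CPM at Pre-Tx, against up to 17.0 in CRC of run NS82. The proliferation gene MKI67 was 0.64 log2 CPM in 1 Pre-xRT library, 7.21 to 8.88 in the others and 6.92 to 7.35 at Pre-Tx. No fit was run without that library, so the proliferation mean decides little.

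Within the hepatocyte group, 25 of 25 genes were lower when adjusted over the list alone, and 0 when adjusted over all genes. Albumin (ALB, ENSG00000163631, chromosome 4, 73397114 to 73421412, plus strand), the main protein of blood plasma, had a log2 fold change of -5.84 (SE 2.51, edgeR adjusted p = 0.213 over all genes), with a normalised read count (CPM) with a median of 4154 at Pre-Tx and 15.7 at Pre-xRT. It was higher at Pre-xRT in 3 of 16 patients with both biopsies. APOA2, an apolipoprotein, and CPS1, the entry enzyme of the urea cycle, had values of -5.51 and -5.52. Of the proliferation genes, 10 of 20 were higher when adjusted over the list alone and 0 over all genes, among them the mitotic kinases AURKB (1.34), PLK1 (0.99) and AURKA (1.34). All 20 had values above 0. Of the 17 histone genes, 12 were higher when adjusted over the list alone, with H3C8 (1.97), H2BC9 (1.62) and H2AC11 (1.58) as those with the smallest p. Histone genes are near-identical copies, so single members are uncertain.

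The 18 general epithelial genes rose by 0.77 and the 19 genes of intestinal lineage by 0.81 (camera adjusted p = 0.0456 and 0.0397). With an estimated correlation both had an adjusted p = 0.992. Both calls were lost with the patient number as a block, at means of 0.42 (camera adjusted p = 0.827) and 0.64 (camera adjusted p = 0.263). Without 1 library they were lost in 25 and 18 of 52 refits, down to 0.62 (camera adjusted p = 0.150) and 0.53 (camera adjusted p = 0.360). Within the CRC libraries of run NS88 both lists fell, by 1.15 (camera adjusted p = 1.0e-06) and by 1.01 (camera adjusted p = 6.1e-04), each with an adjusted p = 0.936 with an estimated correlation. Of the intestinal genes 7 were higher and 1 lower when adjusted over the list alone. The homeobox factors ISX (2.53) and CDX2 (1.96) and the enterotoxin receptor GUCY2C (2.68) were among the 7. The lower gene was the goblet-cell mucin MUC2 (-3.20), whose median went from 1.45 to 6.25 CPM, since 1 Pre-Tx library held 1892 CPM. EPCAM, an epithelial adhesion gene, had 1.02 (SE 0.61, edgeR adjusted p = 0.393).

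Macrophage genes fell (mean -0.60, camera adjusted p = 3.6e-04), as did endothelial genes (-0.44, 0.00368), MHC class II genes (-0.42, 0.0131) and mitochondrial mRNAs (-0.46, 3.6e-04). With an estimated correlation all 4 had an adjusted p = 0.992. The lipopolysaccharide receptor CD14 (-2.08) and the scavenger receptor MARCO (-1.91) were lower when adjusted over the list alone. For MHC class II, 10 of 11 edgeR fold changes were above 0 although the mean of the log values was below 0. Its call was lost in 5 of 52 refits without 1 library, most clearly without that with the fewest genes (-0.41, camera adjusted p = 0.149). Without 1 library the mitochondrial, endothelial and MHC class II means came as near to 0 as -0.17, -0.27 and -0.25. With the patient number as a block and without the library with the fewest genes, MHC class II (-0.45, camera adjusted p = 0.124) and mitochondrial genes (-0.21, camera adjusted p = 0.276) did not pass. Within the CRC libraries of run NS88 the macrophage (-0.0083, camera adjusted p = 0.881), endothelial (-0.084, 0.608) and MHC class II means (0.27, 0.460) did not pass. The mitochondrial mean did (-1.20, 8.2e-05, or 0.936 with an estimated correlation). No fit there left out the Pre-xRT library with 0.06% mitochondrial ribosomal RNA (others 1.06 to 4.77%). With the hepatocyte genes as a covariate, the macrophage, endothelial and MHC class II means were -0.05, -0.04 and 0.01 (camera adjusted p = 0.0909, 0.0909 and 0.281).

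Lymphocyte groups did not pass. Means were 0.04 for T cells, 0.15 for cytotoxic CD8 cells, -0.22 for NK cells, 0.15 for regulatory T cells, 0.08 for B cells, 0.05 for plasma cells and 0.21 each for checkpoint genes and for the 12 chemokines of tertiary lymphoid structures. Only 5 of 17 NK and 3 of 15 B-cell genes were abundant enough to test. When adjusted over the list alone, 7 of 22 genes of the interferon-gamma response were higher, including the peptide transporter TAP1 (1.14), the proteasome subunit PSMB9 (1.08) and the chemokines CXCL9 (2.54) and CXCL10 (1.96), but the group's mean of 0.31 did not pass. In the CRC libraries of run NS88, with 4 at each of these times, genes of interferon-gamma (1.08, camera adjusted p = 3.9e-07), of type I interferon (0.88, 1.5e-05) and of MHC class I (0.45, 0.0105) passed as higher, each with an adjusted p = 0.936 with an estimated correlation. The B-cell chemoattractant CXCL13 had 2.65 (SE 0.96, edgeR adjusted p = 0.140), the protease of cytotoxic granules GZMB 2.14 (SE 0.72, edgeR adjusted p = 0.127) and PDCD1, which encodes PD-1, 2.43 (SE 0.78, edgeR adjusted p = 0.117). CXCL13 and PDCD1 passed over their lists alone, as did the B-cell gene BANK1 (1.43), and of the 12 tertiary lymphoid chemokines 4 did (CXCL9, CXCL10, CXCL13 and CCL8). CD8A had 1.08, CTLA4 1.02, CD274 0.90, FOXP3 -0.07, NCAM1 0.42, KLRD1 -0.33, MS4A1 1.0, CD163 -0.69, MKI67 1.15, CDKN1A 0.17, KRT7 -0.12, COL1A1 -0.41 and ERVK3-1 0.09, and none passed over all genes, while MKI67 passed over the proliferation list alone. IFNG and the lung gene SFTPC had too few counts to be tested in any of the 4 main comparisons.

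The other lists did not pass either. Means were 0.25 for type I interferon, 0.33 for MHC class I, 0.26 for neutrophils, -0.03 for dendritic cells, -0.02 for mast cells, -0.17 for fibroblasts and 0.22 for smooth muscle. They were 0.45 for WNT targets and 0.21 for pancreatobiliary and gastric genes. Both passed as lower in CRC of run NS88 (-0.53 and -0.87, camera adjusted p = 0.0385 and 4.7e-04, or 0.936 each with an estimated correlation). No fit of that run left out its Pre-xRT library of low CDX2. Means over both runs were 0.16 for lung, -0.61 for adipose tissue and mesothelium, 0.40 for skeletal muscle and 0.30 for blood. They were 0.15 for p53 targets, -0.14 for TGF-beta and mesenchymal genes, 0.40 for immediate early genes, 0.36 for heat shock, 0.45 for hypoxia and glycolysis, 0.25 for endogenous retroviruses and 0.26 for innate sensing. The fibroblast genes passed as lower with the patient number as a block (-0.25, camera adjusted p = 0.0114), but not with that block and without the library with the fewest genes (-0.32, camera adjusted p = 0.168). Single members passed over their list alone: DCN (-1.76), BBC3 (0.98) and TNNC2 (2.01). In 7 lists the mean and camera's direction had opposite signs (T cells, cytotoxic CD8 cells, regulatory T cells, B cells, plasma cells, smooth muscle and pancreatobiliary genes had means above 0 and a test direction below), and in 2 (mast cells and lung) the mean and the median did.

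**Figure D1:**
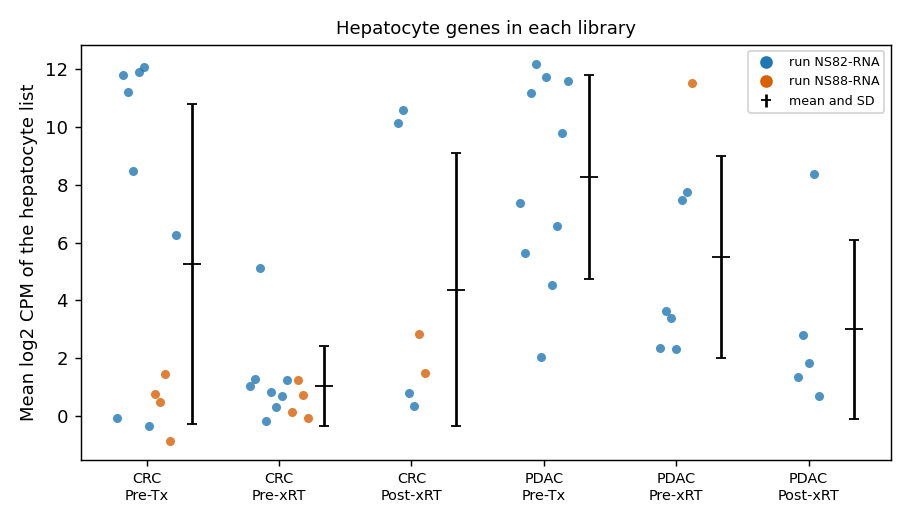
Mean log2 CPM of the 25 hepatocyte genes (vertical axis) in each library (points, coloured by sequencing run) of the 6 groups, with the group mean and SD beside them. CRC Pre-Tx libraries spread from -0.86 to 12.1, whereas CRC Pre-xRT libraries lie between -0.19 and 5.11.

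Within CRC alone, the same step from Pre-Tx to Pre-xRT gave 974 genes past the threshold out of 19186 tested, 847 lower and 127 higher (12 against 12 libraries), and 3639 at an unadjusted p under 0.05. The lower genes were led by liver enzymes and plasma proteins. All 25 hepatocyte genes fell, with a median of -7.85 and a range from -10.2 to -4.42. The fall was not shared by all CRC patients with both biopsies. Within patients the mean of the list changed by -11.2 to -5.00 in some and by -0.73 to 1.61 in the rest. The higher genes included mitotic genes and histones, and also GZMB, CXCL13 and PDCD1. The genes named here for CRC were chosen by extending the rule of the 4 main comparisons after the values were seen.

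Among the falling genes were CYP7A1, the rate-limiting enzyme of bile acid synthesis (ENSG00000167910, chromosome 8, 58490178 to 58500236, minus strand), CYP3A4, a drug-metabolising cytochrome (ENSG00000160868, chromosome 7, 99756960 to 99784265, minus strand), APOA5, CYP1A2, GSTA2, BHMT and the bile acid transporter SLC10A1. CYP3A4 fell by 10.20 on the log2 scale (SE 2.44, edgeR adjusted p = 0.00965), from a median of 11.5 to 0.329 CPM. CYP7A1 had 1 read at Pre-xRT and 2097 at Pre-Tx, a 2466-fold lower share with an interval of 442 to 97430. APOA5 and GSTA2 had 3 reads each at Pre-xRT, with ratios of 1527-fold (522 to 7409) and 1210-fold (414 to 5872) lower. SLC10A1 had 2 reads (1347-fold lower, 373 to 11133). Such intervals here cover counting error only. ALB fell by 8.64 (SE 2.25, edgeR adjusted p = 0.0143), from a median of 2610 to 11.1 CPM. Outside the liver group, CD14 fell by 2.33 (SE 0.68), the proteoglycan DCN by 2.31 (SE 0.66), the lipid droplet gene PLIN4 by 3.62 (SE 1.08), the cadherin CDH2 by 3.20 (SE 0.84) and the pancreatobiliary genes ANXA10 by 5.36 and ONECUT1 by 3.68 (edgeR adjusted p between 0.00938 and 0.047).

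Members of the proliferation and histone groups rose, as did CENPM, which is in neither list. CENPM, a centromere protein (ENSG00000100162, chromosome 22, 41938721 to 41947164, minus strand), rose by 2.45 (SE 0.63, edgeR adjusted p = 0.013), and the kinase PLK1 (ENSG00000166851, chromosome 16, 23677656 to 23690367, plus strand) by 1.60 (SE 0.44, edgeR adjusted p = 0.0193), from a median of 7.66 to 26.3 CPM. CENPM and PLK1 were called in 24 of 24 refits that each left out 1 library. Of 20 proliferation genes, 2 rose over all genes, AURKB being the other (1.89, called in 8 of 24 refits, highest edgeR adjusted p = 0.0956), and 16 of 20 were higher when adjusted over the list alone. Of 17 histone genes, 2 rose over all genes, H2BC7 (2.14, called in 18 of 24 refits) and H2AC11 (2.43, called in 19), and 15 were higher when adjusted over the list alone. As groups, proliferation genes rose by 1.79 and histone genes by 1.67 (camera adjusted p = 1.6e-09 and 6.9e-07), both with an adjusted p = 0.828 with an estimated correlation. These rises accompanied the fall of the hepatocyte group by 4.23 (camera adjusted p = 2.8e-26, and adjusted p = 0.537 with an estimated correlation).

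GZMB (ENSG00000100453, chromosome 14, 24630954 to 24634267, minus strand) rose by 3.07 (SE 0.89, edgeR adjusted p = 0.0289), CXCL13 (ENSG00000156234, chromosome 4, 77511753 to 77611834, plus strand) by 3.93 (SE 1.21, 0.0431) and PDCD1 (ENSG00000188389, chromosome 2, 241849881 to 241858908, minus strand) by 3.40 (SE 0.95, 0.023). Medians stayed low, going from 0.951 to 2.36 CPM for GZMB, 0.655 to 0.670 for CXCL13 and 0 to 0.299 for PDCD1, while the highest Pre-xRT library held 74.3, 109 and 14.2 CPM. Without 1 library their lowest values were 2.21, 1.40 and 1.37 (edgeR adjusted p = 0.131, 0.506 and 0.385). The granule gene GNLY (2.49, edgeR adjusted p = 0.0819), CXCL9 (3.17, 0.072), TAP1 (1.30, 0.0516) and CD8A (1.10, 0.512) did not pass, and without 1 library their lowest values were 0.28, 0.69, 1.0 and -0.42. GNLY and CXCL9 passed in 1 of 24 such refits each and TAP1 in 8. By list, 0 of 17 T-cell, 1 of 13 cytotoxic, 0 of 6 NK, 0 of 3 B-cell and 1 of 14 checkpoint genes rose over all genes. Values above 0 numbered 16, 13, 1, 3 and 14. The T-cell list mean was 1.37 log2 CPM at Pre-Tx and 1.26 at Pre-xRT (highest library 5.27).

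The other leading rises were the follicular dendritic cell gene FDCSP (7.13), HAVCR1 (4.29), RUFY4 (3.86), the peptidylarginine deiminase PADI2 (2.78) and the inducible chaperone HSPA6 (2.62). FDCSP rested on 1 library of the CRC Pre-xRT group with 112 CPM, the next holding 1.21, and without it the value was 1.98 with an edgeR adjusted p of 0.469. The transcription factor gene JUN rose by 1.03 (SE 0.31, edgeR adjusted p = 0.0394), from a median of 79.4 to 181 CPM, and was called in 11 of 24 refits without 1 library (highest edgeR adjusted p = 0.0854). In these refits HAVCR1 and CD14 were called 15 times, PLIN4 14, ONECUT1 9, RUFY4, HSPA6 and DCN 22 and PADI2 23, with a highest edgeR adjusted p between 0.0567 and 0.134, while ANXA10 and CDH2 were called in all 24. When adjusted over the list alone, 3 of 22 interferon-gamma genes, 2 of 13 cytotoxic genes, 2 of 12 tertiary lymphoid chemokines, 2 of 12 heat shock genes and 2 of 3 B-cell genes were higher. Leaving out single libraries moved the number called between 662 and 1187. With the patient number as a block, edgeR called 6 genes in place of 974, all lower (BCHE, CYP7A1, GDF2, SAA4, SAA2-SAA4 and AC007319.1). The 847 lower genes then had a median of -3.14, against -4.40 without the block, and the 127 higher genes one of 1.22, against 1.39. In run NS88 alone edgeR called 0, and with the hepatocyte genes as a covariate it called 1. Within run NS82 it called 1745, with a fit of these 24 libraries alone 315, and DESeq2 called 1686, of which 919 were among the 974.

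**Figure D2:**
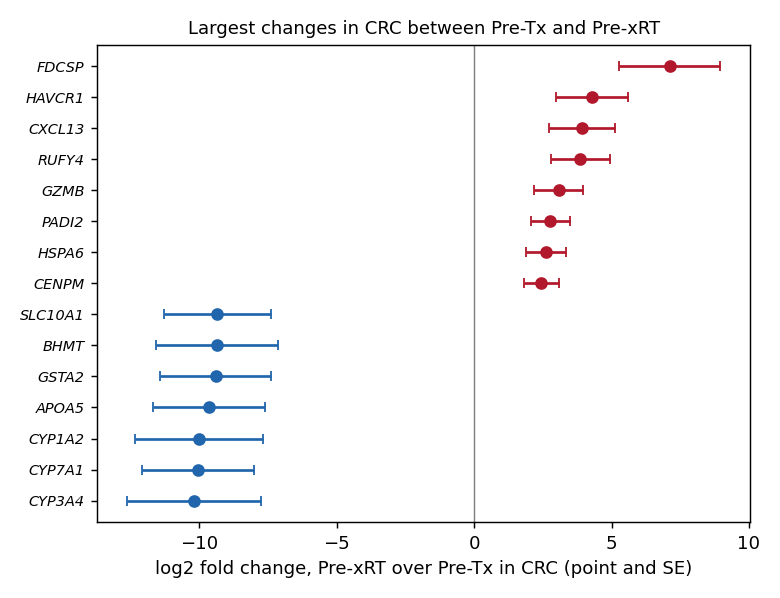
Log2 fold change of Pre-xRT over Pre-Tx in CRC (horizontal axis, point with SE) for the 8 genes with the largest rise and 7 of the 8 with the largest fall past the threshold. The falling genes are liver genes at about -10, and FDCSP, at 7.13, rests on 1 library.

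In PDAC, the same step called 0 genes with edgeR (7 against 10 libraries), with 331 at an unadjusted p under 0.05, and DESeq2 called 4. The hepatocyte genes fell here too, by 2.42 on average (camera adjusted p = 7.0e-15, and adjusted p = 0.972 with an estimated correlation). Epithelial genes rose by 0.82 and proliferation genes by 0.39, while macrophage genes fell by 0.64, each with an adjusted p = 0.972 with an estimated correlation. These 3 calls were lost with the patient number as a block, at means of 0.11 (camera adjusted p = 0.675), -0.01 (0.849) and -0.47 (0.106), and T-cell (0.39, 0.0109) and skeletal muscle genes (0.97, 8.2e-04) passed as higher only with it. Without 1 PDAC Pre-Tx library the proliferation mean was 0.10 (camera adjusted p = 0.489), and without 1 Pre-xRT library the macrophage mean was -0.26 (0.391) and the hepatocyte mean between -3.79 and -1.81. The difference between the cancer types was tested directly. edgeR called 0 genes for it, with 930 at an unadjusted p under 0.05, and DESeq2 called 138. As groups, the proliferation genes differed by -1.40 (PDAC minus CRC, camera adjusted p = 1.8e-06), hypoxia and glycolysis genes by -1.57 (camera adjusted p = 4.2e-07) and hepatocyte genes by 1.82 (camera adjusted p = 1.2e-09), each with an adjusted p = 0.702 with an estimated correlation. Without 1 PDAC Pre-xRT library the hepatocyte difference was 0.44 (camera adjusted p = 0.00168).

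The comparison of Post-xRT with Pre-xRT biopsies concerns the step that added radiation to another site of the same patient. MHC class II genes, genes of macrophages and of matrix-producing fibroblasts, and p53 targets were higher at Post-xRT, and genes of proliferation, histones and tumour epithelium were lower (11 against 19 libraries). MHC class II genes rose by 1.07 (camera adjusted p = 1.1e-08), macrophage genes by 0.93 (camera adjusted p = 5.3e-08) and p53 targets by 0.50 (camera adjusted p = 6.9e-08), and each had an adjusted p = 0.356 with an estimated correlation. Fibroblast genes rose by 0.82 (camera adjusted p = 7.1e-08, and adjusted p = 0.368 with an estimated correlation). In all, 27 of 38 lists passed, 19 higher and 8 lower, and 0 with an estimated correlation. No single gene passed over the 18531 tested with edgeR, with 1204 at an unadjusted p under 0.05; DESeq2 called 6 and limma-voom 1. Within run NS82 alone edgeR called 0 genes, 1882 had an unadjusted p under 0.05 and 22 lists passed.

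All 11 MHC class II, 16 macrophage and 20 fibroblast genes had values above 0 in this comparison. The macrophage genes SIGLEC1 (1.62) and MS4A4A (1.54) were higher when adjusted over the list alone. Type I interferon genes rose by 0.47, interferon-gamma genes by 0.40, TGF-beta genes by 0.47, endothelial genes by 0.47, smooth muscle genes by 0.67 and innate sensing genes by 0.36, with an adjusted p between 0.368 and 0.495 with an estimated correlation. T-cell genes (0.30), regulatory T-cell genes (0.41), checkpoint genes (0.27) and tertiary lymphoid chemokines (0.37) also passed, with an adjusted p between 0.368 and 0.543 with an estimated correlation. The last 4 lost their calls with the patient number as a block, and the T-cell, checkpoint and chemokine means turned to -0.20, -0.21 and -0.24. The block likewise ended the calls of interferon-gamma (-0.05), type I interferon (0.06), fibroblast (0.11), smooth muscle (0.04), endothelial (-0.05), TGF-beta (0.13), innate sensing (0.10), WNT (-0.38), skeletal muscle (0.37), heat shock (-0.20), hypoxia (-0.23) and mitochondrial (0.11) lists. It left MHC class II (0.47, camera adjusted p = 5.1e-04), macrophage (0.49, camera adjusted p = 1.7e-04) and p53 genes (0.57, camera adjusted p = 3.3e-11) past the threshold. Without 1 library, the calls of endothelial (0.11, camera adjusted p = 0.245), smooth muscle (0.39, 0.0782), interferon-gamma (0.27, 0.0514), T-cell (0.19, 0.0888), regulatory T-cell (0.30, 0.0684), checkpoint (0.14, 0.247) and chemokine lists (0.20, 0.192) were lost, and the type I interferon mean came down to 0.29 with its call kept. Leaving out other single libraries raised the T-cell, checkpoint and chemokine means to 0.54, 0.49 and 0.64.

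Of the falling groups, histones had a mean of -1.07 (camera adjusted p = 1.7e-08), intestinal genes -1.15 (6.2e-06), proliferation genes -0.84 (6.2e-06), epithelial genes -0.91 (2.6e-05), hypoxia and glycolysis genes -0.71 (2.1e-04), heat shock genes -0.48 (0.00117), blood genes -0.97 (0.00489) and WNT targets -0.56 (0.0165). With an estimated correlation these had an adjusted p between 0.356 and 0.495. The haemoglobin genes HBB (-3.83), HBA2 (-4.04) and HBA1 (-3.69), of which the last 2 are near-identical, the haem enzyme ALAS2 (-4.28) and SLC4A1 (-3.57) were lower when adjusted over the list alone. All 20 proliferation genes and all 19 intestinal genes had values below 0. Hepatocyte genes, in the opposite direction to the step before, had a mean of 0.70 (camera adjusted p = 0.0118, and adjusted p = 0.641 with an estimated correlation), and adipose genes one of 0.71 (camera adjusted p = 0.0165, and adjusted p = 0.356 with an estimated correlation), with PLIN1 (3.62), PLIN4 (3.70) and FABP4 (2.62) passing over the list alone. Leaving out 1 library took the hepatocyte mean to -0.059 (camera adjusted p = 0.615) and ended the adipose (0.32, 0.152), epithelial (-0.38, 0.0901), blood (-0.73, 0.0546) and WNT calls (-0.34, 0.152), while the intestinal mean came to -0.75 with its call kept. With the block and without the library with the fewest genes the epithelial list did not pass (-0.59, camera adjusted p = 0.0709).

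The p53 group held 5 genes that were higher when adjusted over the list alone. These were ZMAT3 (1.09, SE 0.30), the p53 antagonist MDM2 (1.11, SE 0.30), the mitochondrial reductase FDXR (1.57, SE 0.42), the cell-cycle inhibitor CDKN1A (0.99, SE 0.33) and SPATA18 (1.57, SE 0.55). MDM2 and ZMAT3 were each higher in 8 of 9 patients with both biopsies. Genes named by their small p, none of which passed (edgeR adjusted p = 0.594 for all 6), were MERTK, a receptor for clearing dying cells (1.59, SE 0.38; ENSG00000153208, chromosome 2, 111898479 to 112029561, plus strand), TUB (2.32), FCGBP (3.89), NPTX1 (2.71), the immediate early factor FOSB (2.36) and SUSD5 (2.89). CD8A (-0.31), GZMB (-0.64), PDCD1 (0.19), FOXP3 (1.14), NCAM1 (-1.17), MS4A1 (-1.67), CXCL13 (-1.18), CXCL9 (-0.57), CD163 (1.40), MKI67 (-0.95), EPCAM (-0.91), CDX2 (-2.10), KRT7 (0.71), COL1A1 (1.44), ALB (3.90) and ERVK3-1 (0.26) did not pass over all genes. Immediate early genes rose by 0.26, skeletal muscle genes by 0.52 and mitochondrial mRNAs by 0.31, with an adjusted p between 0.368 and 0.545 with an estimated correlation; DUSP1 (1.42), FOSB and RYR1 (1.93) passed over their lists alone. These 3 calls were lost in 3, 17 and 3 of 52 refits without 1 library, down to 0.11 (camera adjusted p = 0.420), 0.37 (0.224) and 0.032 (0.582). Lists that did not pass were cytotoxic cells (0.01), NK cells (0.19), B cells (0.19), plasma cells (-0.04), MHC class I (0.00), neutrophils (0.16), dendritic cells (-0.15), mast cells (0.18), pancreatobiliary genes (-0.07), lung (0.60) and endogenous retroviruses (-0.36). With the patient number as a block, cytotoxic genes (-0.37, camera adjusted p = 0.0301), plasma-cell genes (-0.65, 0.00925) and dendritic-cell genes (-0.50, 0.0129) passed as lower and lung genes (0.64, 0.0275) as higher. None of these 4 passed with the block once the library with the fewest genes was left out (camera adjusted p = 0.149, 0.0874, 0.0842 and 0.0633). The plasma-cell and pancreatobiliary means lay below 0 with a test direction above, and the cytotoxic mean and median had opposite signs.

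**Figure D3:**
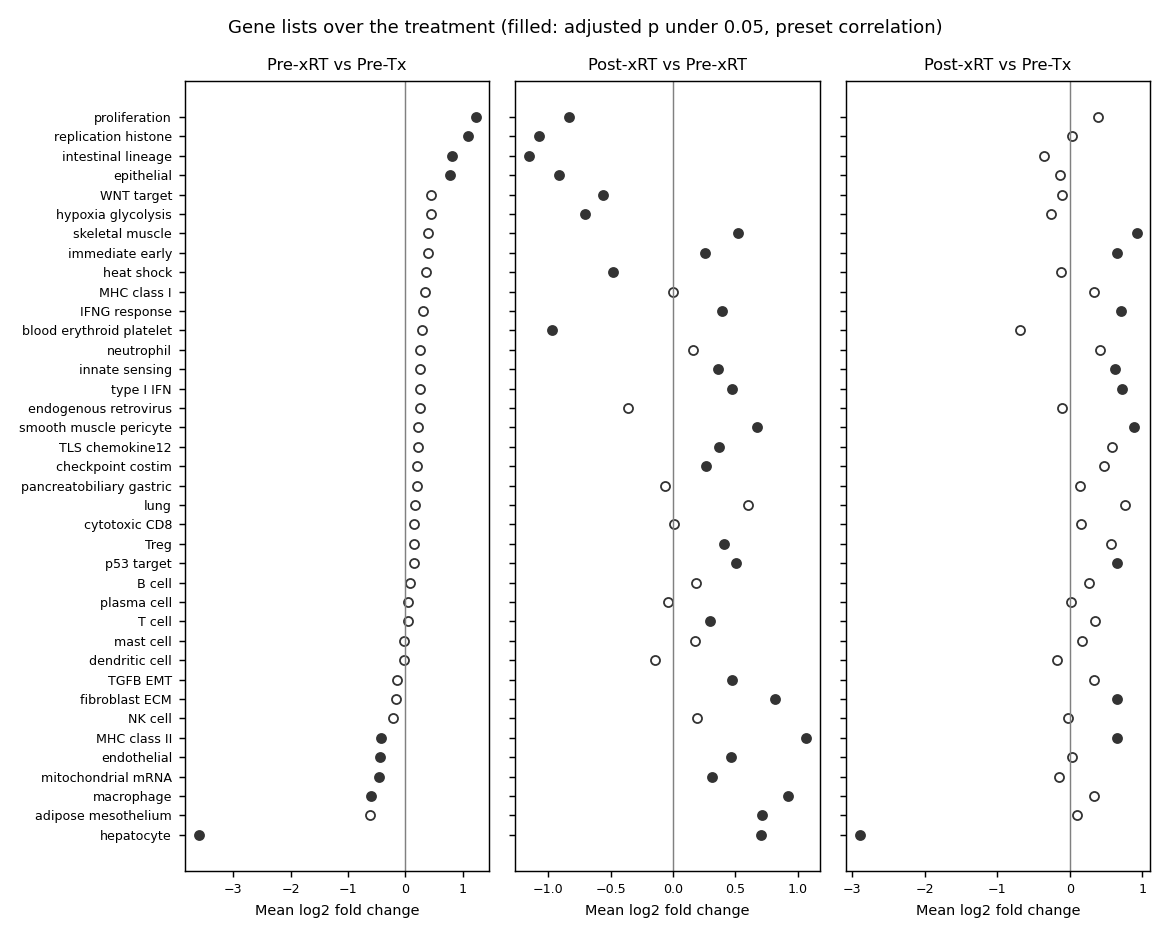
Mean log2 fold change (horizontal axes, 1 scale per panel) of the 38 gene lists in the 3 time comparisons, with filled points for a camera adjusted p under 0.05 at the preset correlation. Proliferation and histone lists lie above 0 from Pre-Tx to Pre-xRT and below 0 from Pre-xRT to Post-xRT, and the hepatocyte list stands at -3.60, 0.70 and -2.90.

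Over the whole course, from Pre-Tx to Post-xRT (11 against 22 libraries), p53 targets, interferon-response genes and immediate early genes were higher and hepatocyte genes lower. The 24 p53 targets rose by 0.65 (camera adjusted p = 4.3e-07), immediate early genes by 0.66 (camera adjusted p = 5.2e-04) and hepatocyte genes fell by 2.90 (camera adjusted p = 1.3e-17), each with an adjusted p = 0.611 with an estimated correlation. Interferon-gamma genes rose by 0.71 (camera adjusted p = 1.9e-04, and adjusted p = 0.814 with an estimated correlation) and type I interferon genes by 0.72 (camera adjusted p = 2.6e-04, and adjusted p = 0.861 with an estimated correlation). Over all genes edgeR called 0, with 1850 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 4 (among them SLC11A1, TDRD9 and FOSB, named after their values were seen). Within run NS82 alone edgeR called 0 genes, 2475 had an unadjusted p under 0.05 and the p53 list stood at 0.76 (camera adjusted p = 6.7e-05).

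Of the p53 targets, 22 of 24 had values above 0 and 8 were higher when adjusted over the list alone. They were FDXR (1.56, SE 0.42; ENSG00000161513, chromosome 17, 74862497 to 74873031, minus strand), the cell-death gene BBC3 (1.14, SE 0.31; ENSG00000105327, chromosome 19, 47220822 to 47232766, minus strand), CDKN1A (1.16, SE 0.32; ENSG00000124762, chromosome 6, 36676460 to 36687339, plus strand), MDM2 (0.92; ENSG00000135679, chromosome 12, 68808176 to 68850686, plus strand), PLK3 (1.36), AEN (0.89), BAX (0.86) and DDB2 (0.88). BBC3 was higher in 10 of 10 patients with both biopsies, CDKN1A and MDM2 in 9 and FDXR in 8. The mean of the list was higher in 9 of 10 patients, by 1.0 on average (two-sided exact sign-flip test p = 0.00586, where 0.00195 is the smallest possible, too large for 1 list by itself to pass an adjustment over 38). Without the pair that holds the library with the fewest genes it was higher in 8 of 9 patients, by 0.64 on average (exact sign-flip p = 0.0117). The list stood at 0.84 with the patient number as a block (camera adjusted p = 3.1e-09). Without that library it stood at 0.51 (camera adjusted p = 3.6e-07), and at 0.58 with the block (camera adjusted p = 8.0e-10). In CRC it rose by 1.10 (camera adjusted p = 2.6e-12, and adjusted p = 0.165 with an estimated correlation; 6 against 12 libraries), and in PDAC the mean was 0.10 (camera adjusted p = 0.432; 5 against 10 libraries). The difference, PDAC minus CRC, was -0.996 (camera adjusted p = 2.3e-05, and adjusted p = 0.702 with an estimated correlation), and -0.65 without 1 CRC Pre-Tx library (camera adjusted p = 7.8e-05).

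**Figure D4:**
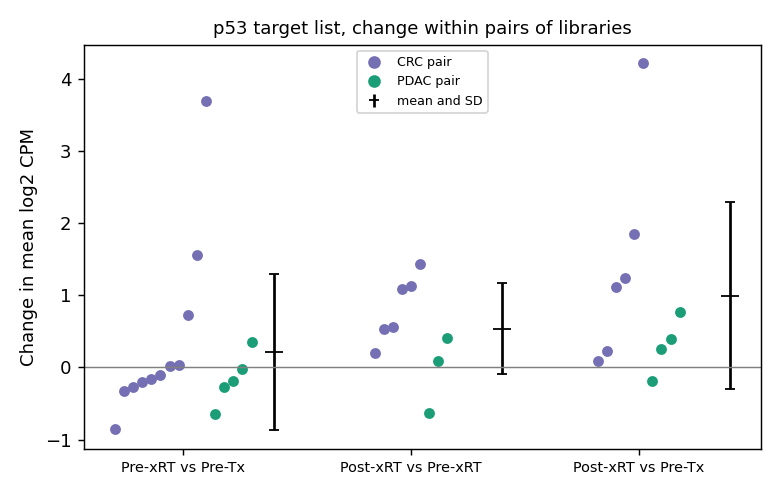
Change in the mean log2 CPM of the 24 p53 targets (vertical axis) within each patient with both biopsies (points, CRC and PDAC), with mean and SD, for the 3 time comparisons. From Pre-Tx to Post-xRT 9 of 10 points lie above 0.

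Innate sensing genes rose by 0.62, MHC class II and fibroblast genes by 0.65 each, smooth muscle genes by 0.89 and skeletal muscle genes by 0.92 over the whole course, with an adjusted p between 0.611 and 0.861 with an estimated correlation. The calls of interferon-gamma (0.32), MHC class II (0.04), fibroblast (-0.14) and smooth muscle genes (0.20) were lost with the patient number as a block, while type I interferon (0.62), innate sensing (0.53) and skeletal muscle genes (1.02) stayed past the threshold. Without 1 library, MHC class II (0.53, camera adjusted p = 0.136), fibroblast (0.41, 0.346), smooth muscle (0.69, 0.164) and skeletal muscle genes (0.78, 0.124) lost the call, in 7, 4, 4 and 13 of 52 refits. In the same paired test blood (-1.01, camera adjusted p = 0.00233), dendritic-cell (-0.50, 0.0108), endothelial (-0.42, 0.00915), plasma-cell (-0.57, 0.0216) and mitochondrial genes (-0.22, 0.0468) passed as lower, which they did not without the block. When the library with the fewest genes was left out too, blood (-1.06, camera adjusted p = 0.0493) and endothelial genes (-0.80, 9.5e-04) passed, and dendritic-cell (-0.58, 0.152), plasma-cell (-0.65, 0.363) and mitochondrial genes (-0.059, 0.922) did not. By smallest p the genes were FOSB (2.76, SE 0.59, edgeR adjusted p = 0.427; ENSG00000125740, chromosome 19, 45467995 to 45475179, plus strand), whose median went from 1.65 to 8.69 CPM, TDRD9 (1.83), DPY19L2 (2.84), RAPGEF3 (2.44) and GON4L (0.84), and none passed. PDCD1 (2.62), the chemokine CCL8 (2.71), the antigen-presentation genes TAP1 (1.09) and NLRC5 (1.29), ZBP1 (1.84), HDC (2.05), MYH11 (2.49), CNN1 (1.89), AQP5 (3.24), NEB (1.40), TNNT3 (2.84), RYR1 (1.46) and MUC2 (-5.19) passed over their lists alone, MUC2 against a Pre-Tx group in which 1 library held 1892 CPM. CD8A (0.77), GZMB (1.5), CTLA4 (1.64), FOXP3 (1.06), CXCL13 (1.46), CXCL9 (1.97), CD163 (0.71), MKI67 (0.21), EPCAM (0.11), CDX2 (-0.14), KRT7 (0.58), COL1A1 (1.03), ALB (-1.93) and ERVK3-1 (0.35) did not pass over all genes. In 4 lists (endothelial, histone, pancreatobiliary and plasma cells) the mean lay above 0 and the test direction below, and in 3 (WNT, endogenous retroviruses and plasma cells) the mean and median differed in sign.

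Within each cancer type edgeR called 0 genes for the steps to Post-xRT. In CRC, 1053 genes against Pre-Tx and 1860 against Pre-xRT had an unadjusted p under 0.05, and DESeq2 called 13 and 446. In PDAC the numbers were 1854 and 789, and DESeq2 called 94 and 26. For the difference between cancer types over the whole course, edgeR called 0 genes, 822 had an unadjusted p under 0.05 and DESeq2 called 12. Hepatocyte genes went opposite ways after Pre-xRT, with a rise by 3.34 in CRC (camera adjusted p = 3.5e-14, and adjusted p = 0.509 with an estimated correlation) and a value of -2.89 in PDAC (camera adjusted p = 9.8e-12, and adjusted p = 0.562 with an estimated correlation). In CRC, 2 of 6 Post-xRT libraries had means of 10.1 and 10.6 log2 CPM and the other 4 lay between 0.36 and 2.85. Without 1 of the 6 it was as low as 2.24 (camera adjusted p = 4.2e-07). The PDAC value went from -4.22 without 1 Post-xRT library to -1.52 without 1 Pre-xRT library (camera adjusted p = 9.3e-05). In PDAC, fibroblast genes rose by 1.33 and checkpoint genes by 0.91 from Pre-Tx to Post-xRT (camera adjusted p = 2.0e-07 and 6.5e-05, and adjusted p = 0.872 for both with an estimated correlation). Their differences from CRC were 1.26 (camera adjusted p = 2.2e-07) and 0.82 (camera adjusted p = 2.7e-04), both with an adjusted p = 0.702 with an estimated correlation. Without 1 PDAC Post-xRT library the fibroblast values were 0.80 (camera adjusted p = 0.0134) and, for the difference, 0.73 (camera adjusted p = 0.00334).

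At baseline, PDAC metastases were compared with CRC metastases to describe the starting difference of the tumour types (10 against 12 libraries, each from another patient). Intestinal genes and WNT targets were lower in PDAC and pancreatobiliary and gastric genes higher. Intestinal genes were lower by a mean log2 value of -1.89 (camera adjusted p = 1.8e-28), and this was the only list of the 4 main comparisons to pass with an estimated correlation (adjusted p = 0.0124). WNT targets had -1.14 (camera adjusted p = 5.2e-13) and pancreatobiliary genes 2.35 (camera adjusted p = 1.6e-08), both with an adjusted p = 0.107 with an estimated correlation. Over 17551 genes edgeR called 0, with 1169 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 93 (48 higher and 45 lower). Within run NS82 alone edgeR called 0 genes, 712 had an unadjusted p under 0.05, and the intestinal, WNT and pancreatobiliary means were -1.93, -1.15 and 2.40.

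The smallest p belonged to KRT7, a keratin of simple duct epithelia (5.0, SE 0.91, edgeR adjusted p = 0.115; ENSG00000135480, chromosome 12, 52232520 to 52252186, plus strand), at a median of 259 CPM in PDAC and 6.01 in CRC. HOXB8 (-5.59, SE 1.11), HOXA9 (-4.36, SE 0.92), FAM83A (9.38, SE 1.95), ANXA8L1 (7.65, SE 1.56), which shares reads with ANXA8, and MIR205HG had the same edgeR adjusted p of 0.115. MIR205HG had 1 read in CRC, for a ratio of 2252-fold with an interval of 404 to 88973. When adjusted over the list alone, 9 of 20 pancreatobiliary genes were higher, among them KRT7, the gastric tight-junction gene CLDN18 (9.08, SE 2.10; ENSG00000066405, chromosome 3, 137998735 to 138033655, plus strand), the mucins MUC5AC (5.66; ENSG00000215182, chromosome 11, 1157953 to 1201138, plus strand), MUC1 (3.87) and MUC16 (5.32), PSCA (4.90) and KRT17 (5.24). CLDN18 had a median of 0.171 CPM in PDAC and 0 in CRC, with a highest library of 465 CPM. Of 18 intestinal genes 0 had values above 0 and 8 were lower over the list alone, including the brush-border protease MEP1A (-5.53, SE 1.20; ENSG00000112818, chromosome 6, 46793390 to 46839782, plus strand), GUCY2C (-3.86), PHGR1 (-4.21), CDX2 (-3.18) and VIL1 (-2.52). Of 14 WNT targets 6 were lower over the list alone, led by the secreted WNT inhibitor NOTUM (-4.70, SE 1.17; ENSG00000185269, chromosome 17, 81952507 to 81961840, minus strand), NKD1 (-3.57) and the stem-cell receptor LGR5 (-3.14).

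**Figure D5:**
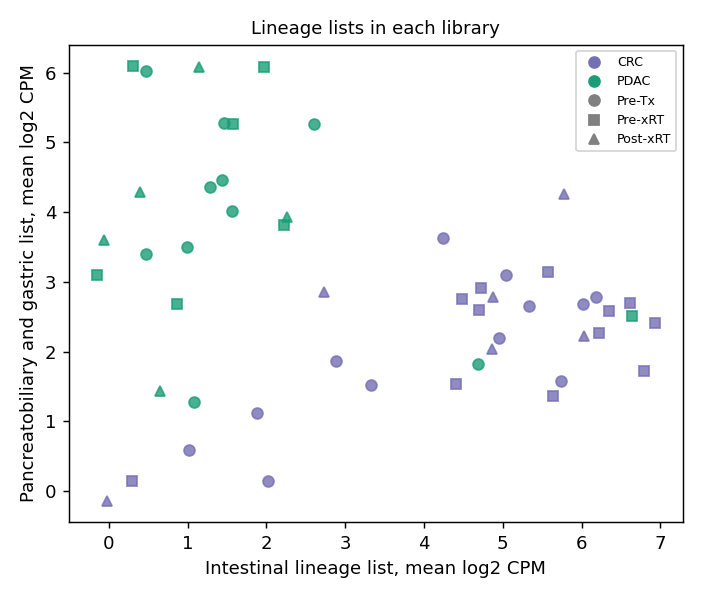
Mean log2 CPM of the 19 intestinal genes (horizontal axis) against that of the pancreatobiliary and gastric genes (vertical axis) in each library, with CRC and PDAC in colour and time points as shapes. Most PDAC libraries lie to the upper left of the CRC libraries, and 1 PDAC library at Pre-Tx (4.68) and 1 at Pre-xRT (6.64) lie among CRC libraries on the horizontal axis.

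Several immune lists passed as lower in PDAC at baseline in camera, which compares a list with the other genes tested. Cytotoxic genes had a mean of -0.52 (camera adjusted p = 5.4e-06), T-cell genes -0.35 (7.5e-06), plasma-cell genes -0.61 (1.5e-05), macrophage genes -0.25 (1.0e-04), MHC class II genes -0.24 (6.6e-04), NK genes -0.36 (0.0169) and tertiary lymphoid chemokines -0.14 (0.0169), with an adjusted p between 0.313 and 0.599 with an estimated correlation. Mitochondrial mRNAs (-0.41) and blood genes (-0.37) were lower too, and proliferation genes higher by 1.21 (camera adjusted p = 9.3e-05), with an adjusted p of 0.457, 0.49 and 0.704 with an estimated correlation. The interferon-gamma and fibroblast lists passed as lower although their means were 0.07 and 0.02, with an adjusted p of 0.884 and 0.882 with an estimated correlation, and the fibroblast median was -0.03. In 11 lists the mean and the test direction had opposite signs, and only these 2 of them passed. Without the run term, mean levels were lower in PDAC for T-cell, cytotoxic, plasma-cell and chemokine genes. They were not lower for macrophage (4.43 log2 CPM against 4.35 in CRC), MHC class II (4.97 against 4.94) and NK genes (1.69 against 1.67). Leaving out 1 library ended the calls of NK (-0.16, camera adjusted p = 0.0861), chemokine (0.16, 0.197), interferon-gamma (0.24, 0.432), MHC class II (-0.30, 0.126), fibroblast (-0.063, 0.562), blood (0.12, 0.292) and mitochondrial lists (-0.20, 0.0880), in 4, 4, 10, 1, 4, 3 and 1 of 22 refits. With their calls kept, it brought the T-cell, macrophage, plasma-cell and WNT means to -0.091, -0.017, -0.21 and -0.68 and the proliferation mean to 0.72, and the cytotoxic mean as low as -0.85. Passing over their lists alone were the T-cell kinase LCK (-2.37), CTLA4 (-2.81), IKZF2 (1.64), H3C8 (-2.86), H2BC9 (-2.72), TNNT1 (5.31), FOS (2.16), CALB2 (4.48) and UPK3B (2.13). CD8A (-0.93), GZMB (-0.61), FOXP3 (0.55), CXCL9 (-1.28), CD163 (-0.83), MKI67 (0.85), CDKN1A (0.63), EPCAM (-1.09), COL1A1 (-0.06), ALB (-0.32) and ERVK3-1 (0.06) did not pass over all genes. The hepatocyte list, with library means from -0.86 to 12.1 log2 CPM in CRC and from 2.03 to 12.2 in PDAC, had a mean of 0.58 and did not pass (camera adjusted p = 0.187).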

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

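All tests of explanations in this part were chosen after the results were seen; only the plan to compare the real labels with other splits of the samples, and the hepatocyte and run NS82 alternatives of the main comparisons, came before.

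10 of 88 groups tested held 1 library apart from the rest by Dixon's test, over 22 measures in the 4 groups of 5 to 10 libraries, where chance gives about 1 in 20 (4.4 here). CRC Pre-Tx and CRC Pre-xRT, with 12 libraries each, were not tested this way. In PDAC Post-xRT, 1 library had the highest hepatocyte mean at 8.36 log2 CPM (next 2.79) and the highest ALB at 13.2 (next 5.96), and the lowest epithelial mean was 2.86 (next 6.39). In PDAC Pre-Tx and PDAC Pre-xRT, 1 library each had an intestinal mean of 4.68 (next 2.60) and 6.64 (next 2.22), and CDX2 at 3.99 (next 0.32) and 6.06 (next 1.77). CXCL13 was highest at 3.64 in 1 library of PDAC Pre-Tx (next 0.46) and at 2.99 in 1 of PDAC Pre-xRT (next 0.72), and CDKN1A was lowest at 4.37 in 1 library of PDAC Pre-xRT (next 5.48). Repeat families, which were left out of the main comparisons and tested only afterwards, held a median of 41.0% of all counts.

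The change over time differed between the cancer types for 14 lists up to Pre-xRT and 11 lists over the whole course by camera's test of the difference, PDAC minus CRC, with an adjusted p between 0.702 and 0.835 with an estimated correlation. From Pre-Tx to Pre-xRT, hypoxia and glycolysis genes (-1.57), proliferation genes (-1.40), histones (-1.37) and immediate early genes (-0.75) were relatively lower in PDAC. Hepatocyte (1.82), blood (0.68), fibroblast (0.47), smooth muscle (0.42), endothelial (0.39), MHC class II (0.38), T-cell (0.35), mitochondrial (0.25), epithelial (0.079) and pancreatobiliary genes (0.057) were relatively higher, the last with a median of -0.18. From Pre-Tx to Post-xRT, hepatocyte (-4.42), histone (-1.29), immediate early (-1.08) and p53 genes (-0.996) were relatively lower in PDAC. Fibroblast (1.26), checkpoint (0.82), regulatory T-cell (0.62), T-cell (0.59), tertiary lymphoid (0.58), WNT (0.57) and MHC class II genes (0.45) were relatively higher. With the patient number as a block, the epithelial and pancreatobiliary calls (-0.42 and -0.23) and, over the whole course, the WNT and histone calls (-0.12 and -0.24) were lost. It gained 3 calls up to Pre-xRT, heat shock (-0.84), macrophage (0.13) and skeletal muscle genes (0.45), and 5 over the whole course, interferon-gamma (0.39), epithelial (0.62), adipose (-1.43), lung (-1.57) and neutrophil genes (-1.53). Leaving out 1 library ended the MHC class II, blood, endothelial, epithelial, immediate early, mitochondrial, pancreatobiliary or smooth muscle call up to Pre-xRT (highest camera adjusted p by list from 0.0860 to 0.823). Over the whole course it ended the MHC class II, tertiary lymphoid, T-cell, regulatory T-cell, WNT or histone call (0.0555 to 0.305).

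The first pattern weighed is the set of genes lower at Pre-xRT in CRC. The 822 called genes outside the hepatocyte list had a median log2 fold change of -4.33 (jackknife SE 0.588), and with the hepatocyte list as a covariate it was -0.55, while their median SE went from 1.14 to 0.705, so the calls ended because the folds shrank. A lower share of liver tissue in the Pre-xRT biopsies may thus account for most of it, which is in line with albumin at a median of 2610 CPM at Pre-Tx. Run and depth are not the whole cause, since within run NS82 the 847 lower genes had a median of -5.04 against -4.40, nor is the library with the fewest genes, without which it was -4.31. In run NS88, whose 4 CRC Pre-Tx libraries had hepatocyte means of at most 1.45 log2 CPM, those of the lower genes that could be tested had a median of -0.39. Whether the biopsied organ changed between time points or the metastases held less liver cannot be decided here, as the site is not given in the sources used here.

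The next pattern is the rise of p53 targets from Pre-Tx to Post-xRT, 0.65 (jackknife SE 0.274). With the epithelial list as a covariate it was 0.641, with the hepatocyte list 0.691 and within run NS82 0.758, with camera adjusted p from 1.3e-09 to 6.7e-05, which argues against a changed share of tumour cells, of liver or the run as the whole cause. Of 100 splits within patient numbers 1, the real one, gave a mean as large (0.650, the highest other 0.624), and 2 of 100 drawn freely within cancer types did (highest other 0.664), which excludes chance only for this list taken alone. It was picked among 38 lists after its value was seen, and 4 of them had a share of splits under 0.05 where 1.9 are to be had by chance, so chance stays open after that choice. Whether drugs, radiation or a changed cell type not covered by the lists lies behind it was not tested and stays open.

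The last pattern is the rise of proliferation and histone genes from Pre-Tx to Pre-xRT (1.22 with jackknife SE 0.479, and 1.10 with jackknife SE 0.420). Within run NS82 the means were 1.71 and 1.38, against the run as the whole cause. In CRC of run NS88, 1 Pre-xRT library had MKI67 at 0.64 log2 CPM against 7.21 to 8.88 in the others. No fit left it out there, and the list means were -0.033 and 0.60. With the epithelial list as a covariate they were 0.653 and 0.680 and with the hepatocyte list 0.757 and 0.931, all past the camera threshold, but, given their SE, too close to the middle between no change and the original means to tell a larger tumour share from more division per tumour cell. Of 100 splits 1 gave a mean as large for each, the real one (highest others 1.10 and 0.957), which excludes chance only for each list taken alone, since 3 of 38 lists had a share under 0.05 where 1.9 are to be had by chance. The patient block kept both calls, but the exact sign-flip p within 16 patients was 0.0257 and 0.0269 and did not pass over 38 lists, so chance stays open after the choice among lists.

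Other splits of the same libraries were compared with the real labels. Within patient numbers, labels were shuffled so that each split parts as many pairs (35) as the real one. For Pre-xRT against Pre-Tx, 2 of 30 splits called as many genes as the real 1 (highest other 2), so chance cannot be excluded for that call, whereas 1 of 30 had as many genes at an unadjusted p under 0.05 (3204, highest other 2684). For CRC alone 1 of 30, the real one, called as many (974, highest other 844). This excludes chance only for this contrast taken alone, at the smallest share that 30 splits can give, and another split came near. The CRC contrast was singled out after its values were seen, so chance stays open after that choice. Splits drawn freely within cancer types parted 15 to 27 pairs and called at most 539 genes in CRC.

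For the remaining comparisons chance could not be excluded even for each taken alone, by splits within patient numbers or, at baseline, of the cancer type labels. The splits with as many genes at an unadjusted p under 0.05 were 15 of 30 for Post-xRT against Pre-xRT (1204, highest other 3063), 4 for Post-xRT against Pre-Tx (1850, highest other 2592) and 18 of 100 for the baseline contrast (1169, highest other 3819). In CRC they were 11 of 30 for Post-xRT against Pre-Tx (1053, highest other 2693) and 6 against Pre-xRT (1860, highest other 3305). In PDAC they were 9 for Pre-xRT against Pre-Tx (331, highest other 491), 10 for Post-xRT against Pre-Tx (1854, highest other 2947) and 20 against Pre-xRT (789, highest other 2581). For the differences between cancer types they were 5 (930, highest other 1286) and 16 (822, highest other 2771). The count of lists that passed was reached in 80 of 100 splits for Pre-xRT against Pre-Tx (9, highest other 22), 5 for Post-xRT against Pre-xRT (27, highest other 28), 89 for Post-xRT against Pre-Tx (10, highest other 27) and 32 at baseline (15, highest other 28). Drawn freely within cancer types, 1 of 100 splits, the real one, reached 27 lists for Post-xRT against Pre-xRT (highest other 25), so both ways of splitting differ on whether chance can be excluded there. Some splits called many genes where the real labels called 0. Within patient numbers they called up to 282 for Post-xRT against Pre-xRT and 627 for Post-xRT against Pre-Tx, and drawn freely up to 1018 and 105. Free splits also called up to 647 and 323 in PDAC for Pre-xRT and Post-xRT against Pre-Tx, and 1226 for the difference of the cancer types up to Pre-xRT, and splits at baseline up to 135. What makes these splits call many genes was not tested. By list, within patient numbers and at baseline, 3, 1, 4 and 2 of 38 means in the 4 main comparisons were matched in a share of splits under 0.05, with 1.9 to be had by chance.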

How the results depend on the processing

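The fits without the library with the fewest genes, with the authors' size factors or with the epithelial list as a covariate, the blocked fits without libraries, the further CRC fits, run NS88 among them, and the refits of lists without single libraries were chosen after seeing the data, and the other alternatives before.

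For Pre-xRT against Pre-Tx, where edgeR called 1 gene, the count was 2 with RLE scaling, with the authors' size factors, with only these 2 time points or without the library with the fewest genes, and 9 with the conflicting library kept. It was 1463 with DESeq2, 69 with no filter, 0 with the stricter filter, 343 with no run term, 1912 within run NS82, 1495 without the libraries of low depth and 0 with the hepatocyte list as a covariate. With the patient number as a block it was 3, with the block as a correlation in limma 750, and with block and hepatocyte list 0. Leaving out the shallow libraries removes most of run NS88, and the hepatocyte covariate removes what moves with that list. For the other settings the cause was not tested.

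For Post-xRT against Pre-xRT (0 called), DESeq2 gave 6, limma-voom 1, no filter 85, the hepatocyte covariate 1 and the block as a correlation 1. For Post-xRT against Pre-Tx (0 called), DESeq2 gave 4, no filter 56 and the hepatocyte covariate 4. At baseline (0 called), DESeq2 gave 93, no run term 1 (KRT7), the hepatocyte covariate 1 (MIR205HG) and the contrast at Pre-xRT 405. In CRC from Pre-Tx to Pre-xRT (974 called), DESeq2 gave 1686, the patient block 6, the same block without the library with the fewest genes 8, the hepatocyte covariate 1, run NS82 1745, the CRC libraries of run NS88 0 (4 against 4, fewer genes tested) and a fit of these CRC libraries alone 315. All 6 blocked calls were among the 974. RLE scaling (1059), the authors' size factors (1033), no filter (786), the libraries of low depth left out (1290) and the library with the fewest genes left out (955) stayed within 1.5 times. For the steps to Post-xRT in CRC (0 called), DESeq2 gave 13 from Pre-Tx and 446 from Pre-xRT and no filter 3 and 12. In PDAC, DESeq2 gave 4, 94 and 26, and for the differences between cancer types 138 and 12, where edgeR called 0. The cause was not tested for these tools and filters. The patient block changed no other count of genes called.

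Leaving out single libraries gave 662 to 1187 genes in CRC from Pre-Tx to Pre-xRT and 0 in each refit without 1 of the 11 Post-xRT libraries or, within PDAC and for its difference from CRC, without 1 of its 5. The number of lists passing went from 6 to 11 (9 with all libraries) for Pre-xRT against Pre-Tx, from 20 to 28 (27) for Post-xRT against Pre-xRT, from 6 to 18 (10) for Post-xRT against Pre-Tx and from 11 to 20 (15) at baseline. Calls near the threshold were lost on leaving out any of many single libraries, as for the epithelial genes (camera adjusted p = 0.0456) in 25 of 52 refits of Pre-xRT against Pre-Tx (highest 0.15) and the checkpoint genes (0.0481) in 23 of 52 of Post-xRT against Pre-xRT (highest 0.247). With an estimated correlation 0, 0, 0 and 1 lists passed in the 4 main comparisons, since the estimate allows genes of a list to move together. With the epithelial covariate 5 lists passed for Pre-xRT against Pre-Tx, with the hepatocyte covariate 18 for Post-xRT against Pre-Tx, and at Pre-xRT 9 in the contrast of cancer types (0 with an estimated correlation). With the patient block 15 passed for Post-xRT against Pre-xRT, and without the library with the fewest genes that block gave 10, and 5 for Pre-xRT against Pre-Tx. In the 4 main comparisons and in the within-type tests printed in the report, the block changed no call of a list other than those given there.

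Some directions turned. With the patient block, T-cell, checkpoint and tertiary lymphoid means for Post-xRT against Pre-xRT were -0.20, -0.21 and -0.24, and -0.21, -0.22 and -0.26 without the library with the fewest genes. For Post-xRT against Pre-Tx the blocked fibroblast mean was -0.14 (-0.22 without that library). The blocked MHC class II mean (0.045) and smooth muscle mean (0.20, or -0.19 without that library) had a test direction below 0. Within the cancer types the block turned the test direction of epithelial (0.094), heat shock (0.18) and type I interferon genes (-0.042) in PDAC and of fibroblast genes in CRC (-0.22) for Post-xRT against Pre-xRT, and of the histone difference over the whole course (-0.24). In refits without 1 library the direction turned once each for epithelial genes in CRC (means from -0.70 to 0.70 for Post-xRT against Pre-Tx and from -1.60 to -0.032 against Pre-xRT) and in PDAC (-1.12 to 0.082 against Pre-xRT) and for the epithelial and mitochondrial differences up to Pre-xRT (-0.56 to 0.38 and -0.34 to 0.51). Mitochondrial mRNAs turned to -0.049 for Post-xRT against Pre-xRT within run NS82. In the contrast of cancer types at Pre-xRT in place of baseline, the camera means of T-cell (0.071), NK (0.33), MHC class II (0.55), fibroblast (0.66) and blood genes (0.45) lay above 0 and that of proliferation genes at -0.99 (camera adjusted p = 6.0e-06). For T-cell and MHC class II genes edgeR's fold changes went the other way, with medians of -1.49 (1 of 17 genes above 0) and -0.55 (0 of 11). Of NK genes 3 of 6 lay above 0 in edgeR, of fibroblast genes 15 of 20 and of blood genes 7 of 7. In CRC with the hepatocyte covariate, these falling genes turned: CYP3A4 (0.31), ONECUT1 (0.036), APOA2 (0.37), APOB (0.020), TF (1.30), AHSG (0.35), F2 (0.68), APOA1 (0.088), TAT (0.76), ASGR1 (1.19) and TTR (1.80). All of them but ONECUT1 belong to the covariate's own list. APOB also turned within run NS88 (0.38). For ONECUT1 and the other turns of direction the cause was not tested.

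Of 5513 values for 156 named genes in CRC, 5048 kept direction and side of the threshold, 310 lost the call, 51 gained it and 92 moved. For list means, 458 of 529, 1436 of 1591, 540 of 589 and 354 of 420 values kept both in the 4 main comparisons, and 71, 148, 44 and 60 lost the call with the same direction. Depth limits the weakest statements, since the libraries of run NS88 held a median of 800636 gene counts, IFNG and most B-cell and NK genes were not testable, and at 4 fold the simulated CRC contrast found 72% of genes.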

Other observations

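The contrast of the cancer types was repeated at Pre-xRT, an alternative planned before the data were examined whose genes were named after their values were seen. Here edgeR called 405 genes (333 higher in PDAC and 72 lower; 7 against 12 libraries), against 0 at Pre-Tx. Among the higher genes were keratins and mucins: KRT7 by 6.44 on the log2 scale (SE 0.94, edgeR adjusted p = 0.00281), KRT13 by 10.3, KRT4 by 8.50, MUC6 by 6.78, MUC16 by 6.47 and MUC5AC by 6.28. SERPINB3 (8.14) and PSCA (6.66) were higher too. ANXA8, which shares reads with ANXA8L1, had 8.73. Of 19 pancreatobiliary genes 8 were higher over all genes and 10 over the list alone. NOTUM, a secreted WNT inhibitor, was lower (-6.02, SE 1.55, edgeR adjusted p = 0.046), as were MALRD1 (-6.52) and RIMBP2 (-5.74). The distal homeobox gene HOXD13 and the opioid receptor OPRD1 had 0 reads in PDAC and were at least 32.0-fold and 93.3-fold lower, LCN15 was lower by a ratio of 370 (102 to 3062) on 2 reads, FZD10 by 148 (40.7 to 1220) on 2 and the cartilage collagen COL2A1 by 81.0 (27.5 to 395) on 3. Hepatocyte genes were higher in PDAC at this time, 12 of 25 over all genes and 25 over the list alone, with a median of 5.21.

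Repeat families were tested like genes after the data had been seen, with the scaling of the genes. Of 1304 families (1298 at baseline) edgeR called 0 in the 4 main comparisons, with 130 (Pre-xRT against Pre-Tx), 165 (Post-xRT against Pre-xRT), 131 (Post-xRT against Pre-Tx) and 66 (baseline) at an unadjusted p under 0.05 and medians of -0.16, 0.38, 0.22 and 0.03. Without the library with the fewest genes, 1 of 1301 families was called, lower for Pre-xRT against Pre-Tx (93 at an unadjusted p under 0.05), and 0 in the others. No other tool was run on them. With the patient number as a block the first 3 counts were 46, 3 and 52. The 44 families of HERV-K, a retrovirus group in the human genome, gave 0 calls, with 9, 2, 2 and 1 at an unadjusted p under 0.05.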
